A study of Rattus norvegicus albus with 6 samples.

How the data were processed

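Primary hepatic stellate cells of rats were profiled on 6 Affymetrix whole-transcript arrays, 1 for each of 3 treatments and 1 for each treatment's own control. Per the labels, total RNA was extracted with a silica column kit, copied into single-stranded DNA targets, fragmented and labelled with biotin. The RNA on an array was pooled over 3 to 4 animals, so every group holds 1 array and no array has a replicate. The pairing of each treatment with its control comes from the labels.

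The deposited values are log2 expression values, 1 per probe set and array, made with RMA in Affymetrix Expression Console per the submitters' processing notes. RMA subtracts background, brings the arrays to a common distribution and summarises the probes of each probe set on the log2 scale. The deposited columns nonetheless differed in their medians and in values near the floor, given below, and the reason is not given in the sources used here. The software versions and the annotation release used for the summary are not given in the sources used here. The values were used as deposited, and all 6 columns of array values were used. They run from 4.00 to between 13.5 and 13.8, and a soft floor stands at 4. Between 49 and 382 of the 26988 probe sets lay within 0.01 of that floor on an array. The array medians were 7.01 (Ad.DKK-1), 7.11 (Ad.GFP), 7.11 (ICG-001), 7.28 (vehicle for ICG-001), 7.15 (FJ9) and 7.15 (vehicle for FJ9). Over all 26988 probe sets, the median of the ICG-001 array thus differed by −0.17 from that of its vehicle, and the median of the Ad.DKK-1 array by −0.09 from Ad.GFP. Centring each array on its median takes these amounts from every difference, also for genes that did not share the shift. No detection calls were used. The number of arrays limits the precision.

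Probe sets were named through the platform annotation. It listed 15415 of the 26988 probe sets, of which 15092 had 1 gene symbol and 323 had several, and the other 11573 are unnamed here. Entrez identifiers of 15062 probe sets matched the RefSeq gene table of the assembly GRCr8, and 0 symbols changed on matching. That assembly served for names alone, and no coordinates are given because the build behind the array design is not given in the sources used here. Of 14322 named genes, 497 had several probe sets, and the probe set with the highest mean over the 6 arrays stood for the gene. Genes in the lowest 30% of mean level (up to 6.39) were left out, which kept 10025 genes.

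For each treatment the log2 difference of the treated array minus its own control was taken for each gene, and genes at least 1.5-fold higher or lower were counted. With 1 array on each side there is no test and no p-value for a single treatment. The difference between the vehicle arrays, FJ9's vehicle minus ICG-001's vehicle, was counted the same way as the nearest available measure of how far untreated pools differ. Genes past 1.5-fold in all 3 treatments were sorted into the 2 same-direction and 6 mixed sign patterns, beside the numbers expected of independent lists. The 3 comparisons share no array. The only test was limma (lmFit and eBayes with a trend, two-sided, Benjamini-Hochberg adjusted p under 0.05) of treated against control across the 3 pairs, with the pair as a block. The treatments are not replicates of each other, so limma tests the mean difference over the 3 treatments and never the effect of any treatment alone. Large differences in some treatments can carry a call without a change in the others. Its standard errors lean on the spread pooled over genes, since the design leaves 2 residual degrees of freedom for a gene.

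For 16 pathway lists and 7 lists of cell type markers, the median log2 difference of the members past the level filter was set against the medians of 10000 random lists of the same size, matched on mean level in 20 bins. A list is called below or above where its median lay outside the central 95% of those random lists. This describes the arrays and tests no condition, because the members of a list are not independent.

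The groups, tests, alternatives, lists and the rule for named genes were fixed before the data were examined. The rule names the 12 largest increases and 12 largest decreases of each comparison among filtered genes past 1.5-fold, the 12 higher and 12 lower genes with the largest smallest change over the 3 treatments, and up to 4 members of each list per comparison with the largest absolute change. It also always names Dkk1, Ctnnb1, Axin2, Lef1, Myc, Ccnd1, Birc5, Scd, Scd1, Scd2, Acta2, Col1a1, Pparg and Ndn. Symbols of uncharacterised loci, microRNAs, small nucleolar and ribosomal RNAs, and olfactory and vomeronasal receptors under their older prefixes, are counted and not named, and probe sets with several genes or none are not named. The rule gave 265 genes, of which 10 had several probe sets. Birc5, Scd1 and Acta2 had no probe set with that symbol alone and were not analysed under these symbols. Whether a gene is measured under another symbol, such as Scd for Scd1, was not checked. A further 5 lists were chosen after the data were seen and stand in the closing section.

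The procedures were tested on simulated data. For limma over 10025 genes, simulated shared changes were recovered for 0 of 50 genes changed 1.5-fold, 2 of 50 changed 2-fold, 32 of 50 changed 4-fold and 43 of 50 changed 8-fold, with 0 false calls. Each simulated gene took its own residual spread, estimated from 2 degrees of freedom, as its true spread. The recovery and false-call numbers describe that setting and need not hold for the real arrays. For lists of 25 genes, 13 of 200 lists without a shift lay outside the central 95%, and 176 of 200 lists shifted by 0.5 did. The simulated genes varied independently, which members of a real list do not, so the rate without a shift is too low for real lists. Between the untreated vehicle arrays 3 of the 23 lists lay above and 9 below. Alternatives covered a 2-fold threshold, no level filter or a 50% filter, the mean of all probe sets of a gene, and centring, repeated quantile normalization or a loess correction (span 0.4) of the deposited values. They also covered the other vehicle array or the mean of both, and limma without the block, without the trend, at adjusted p under 0.1 or without each pair in turn. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.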

Results

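Rat hepatic stellate cells, the fat-storing liver cells that turn into matrix-producing myofibroblasts in fibrosis, were grown for 7 days on plastic with 10% serum until fully activated. They then received 1 of 3 treatments that block canonical Wnt signalling at different steps. DKK-1, a secreted antagonist that binds the Wnt co-receptors LRP5 and LRP6, was delivered by adenovirus (Ad.DKK-1) and compared with a virus carrying green fluorescent protein (Ad.GFP). Both viruses were given at 200 infectious units per cell (MOI 200) for 24 h in 5% serum, followed by 24 h without serum. ICG-001, which blocks the binding of β-catenin to the coactivator CBP, was given at 10 µM, and FJ9, which blocks the binding of Dishevelled to Frizzled, at 200 µM. Each compound was applied for 24 h without serum and compared with its own vehicle array. The series asks which genes the canonical Wnt pathway regulates in these cells. There were 6 arrays, 1 per group, each of RNA pooled from 3 to 4 rats, so no difference given below has a replicate check. All differences are treated minus own control on the log2 scale.

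Of 10025 genes, 3531 lay at least 1.5-fold from the control under Ad.DKK-1, 2581 under ICG-001 and 2644 under FJ9, against 766 between the vehicle arrays. The standard deviation of the differences over genes was 0.68, 0.56, 0.63 and 0.34 in the same order. Their median over these genes was −0.07, 0.01, 0.01 and 0.02 before any centring. Centring on the medians of all probe sets shifts the medians for ICG-001 and the vehicle arrays further up. The counts with median centring given below carry that shift.

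The array labelled Ad.DKK-1 was compared with Ad.GFP to ask what DKK-1 changes. Dkk1 itself read 6.01 on the array labelled Ad.DKK-1 and 5.85 on Ad.GFP, a difference of 0.16, and read between 5.88 and 6.83 on the other 4 arrays. Its mean level fell under the level filter. The labels do not say which species' DKK-1 the virus carries or which part of the transcript it contains, so this probe set does not check the label. Axin2, a feedback target that Wnt signalling induces, differed by −1.96 and Ccnd1, which encodes cyclin D1, by −0.98. Nkd1, another feedback inhibitor of the pathway, differed by −1.29. Myc, often listed as a Wnt target, went the other way at 1.03, as did Fosl1 at 2.03 and Twist1 at 1.67. Over the 16 measured members of the canonical Wnt target list, 4 were at least 1.5-fold higher and 6 lower, and the median of −0.11 lay at percentile 40.4 of random lists. The Wnt pathway component list had a median of −0.34 and was called below, with 17 of 43 members lower and 1 higher, among them the secreted antagonists Frzb (−2.09), Sfrp1 (−1.81) and Dkk3 (−1.50). The same list differed by −0.13 between the vehicle arrays and was called there too.

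Under Ad.DKK-1, 1449 genes were at least 1.5-fold higher and 2082 lower. Centring each array on its median turned that split to 1874 higher and 1681 lower. The largest increases were led by Derl3, which acts in the degradation of misfolded proteins of the endoplasmic reticulum (4.91), and Abcb1a, the multidrug efflux pump (4.10). They also included Myo16 (3.44), the secreted stanniocalcin Stc2 (3.15), Ggct of glutathione turnover (3.09), the endoplasmic reticulum protein Creld2 (2.97) and Cth, which makes cysteine (2.81). The stress pseudokinase Trib3 (2.76), Ddit3, which encodes CHOP (2.73), Or55b10 (2.70), the natriuretic peptide gene Nppc (2.67) and Cptp (2.54) completed the 12. The unfolded protein and amino acid response list had a median of 1.12, above all 10000 random lists, with 33 of 38 members at least 1.5-fold higher and 1 lower, and its vehicle difference was 0.01.

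The largest decreases under Ad.DKK-1 were Igfbp5 (−3.91), the cyclin Ccna1 (−3.90), the complement gene C7 (−3.89) and Mx1, an interferon-induced antiviral GTPase (−3.30). Serpina3n (−3.16), Slc44a3 (−3.16), Rgs5 (−3.12), the cell cycle repressor E2f8 (−3.06), Alox15 (−3.05), Ifit3 (−2.97), G0s2 (−2.96) and Pde7b (−2.94) followed. The interferon response list had a median of −1.42, with 24 of 32 members lower and 1 higher, including Mx2 (−2.90) and the ubiquitin-like Isg15 (−2.71). Mx1 and Mx2 are related in sequence, so their probe sets may share signal. The matrix protease list was called below at −1.04, with 16 of 22 members lower and none higher, among them the urokinase Plau (−2.16), Adamts2 (−1.77), Adamts4 (−1.75) and the inhibitor Timp1 (−1.64). Collagens and other matrix genes had a median of −0.59, with 16 of 31 lower, led by Fbln1 (−2.66), elastin Eln (−1.81), lumican Lum (−1.79) and Mfap4 (−1.61). Col1a1, the main fibrillar collagen gene, differed by −0.19. Myofibroblast genes had a median of −0.36 with 9 of 26 lower, led by Postn (−1.87), Loxl1 (−1.47), S100a6 (−1.17) and S100a4 (−1.12), and this call ended with loess correction (percentile 3.16).

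Genes of lipid synthesis were also lower under Ad.DKK-1. Cholesterol synthesis and uptake had a median of −1.02, with 15 of 20 members lower and 1 higher, led by Tm7sf2 (−1.99), Acat2 (−1.50), Dhcr7 (−1.48) and Hsd17b7 (−1.37). Fatty acid synthesis and desaturation had a median of −0.69, with 11 of 20 lower and 4 higher, led by the stearoyl-CoA desaturase Scd (−2.38), Fads2 (−1.94), Fads1 (−1.92) and Acss2 (−1.55). The list of quiescent stellate cell and adipogenic genes was called below too, at −0.42 with 9 of 20 lower and 1 higher, among them Rbp4 (−1.91), the growth factor Hgf (−1.66), lipoprotein lipase Lpl (−1.44) and Fabp4 (−1.41). Pparg, a regulator of the quiescent state, was under the level filter and differed by 0.31, and Ndn, a neuronal growth suppressor, differed by −0.96. Lists of cell cycle (−0.12), chemokines and NF-kB targets (−0.04), oxidative stress (−0.05), p53 targets (−0.12), glycolysis and hypoxia (−0.25), and YAP and serum-response genes (−0.10) lay inside the central 95%. For cell cycle genes this changed without the level filter, where the median was −0.67, below all random lists. Ctnnb1, the gene of β-catenin, differed by −0.39.

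ICG-001 was compared with its vehicle to ask which genes need the β-catenin and CBP partnership. Axin2 differed by −0.13 and Ccnd1 by −0.18, both within the 1.5-fold limits, and Myc by 0.75. The Wnt target list had a median of 0.07, with 6 of 16 members higher, led by the hyaluronan receptor Cd44 (1.58), Fosl1 (1.02) and Jun (0.99), and 3 lower, among them Nkd1 (−1.0025). The component list (−0.08) lay inside the central 95%, although its mean of −0.18 was called below (percentile 1.69), while Sfrp1 (−2.40), Frzb (−1.19), the receptor Fzd1 (−1.01) and the ligand Wnt5a (1.21) were its largest differences. Ctnnb1 differed by 0.19. Lef1, under the level filter, differed by −1.02 here and by 1.03 under Ad.DKK-1.

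In all, 1267 genes were at least 1.5-fold higher and 1314 lower with ICG-001. Median centring turned this to 2218 higher and 754 lower, and 835 higher and 739 lower genes were past 1.5-fold from both vehicle arrays. The largest increases were St8sia2, which builds polysialic acid (3.42), the neurofilament gene Nefm (3.08), Cth (2.77), Nppc (2.71), Flrt3 (2.64), Hopx (2.58) and the protease Pappa (2.41). Efnb2 (2.36), Slc7a8 (2.30), Slc35f2 (2.29), Adamtsl5 (2.24) and the metalloproteinase inhibitor Timp3 (2.22) completed them. The unfolded protein and amino acid response list had a median of 0.53, above all random lists, with 18 of 38 members higher and 2 lower, led by the transcription factor Atf3 (1.79), the phosphatase subunit Ppp1r15a (1.70), Trib3 (1.66) and the serine synthesis enzyme Psat1 (1.47). The p53 target list was called above at 0.36, with 5 of 22 higher and none lower, led by Aen (1.19) and Gadd45a (0.95). YAP and serum-response genes were called above at 0.36 with 8 of 27 higher and 5 lower, for example Dusp1 (1.51) and the endothelin gene Edn1 (1.40) against Nt5e (−1.71). With the other vehicle this median was 0.20, at percentile 94.6, and no longer called.

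The largest decreases with ICG-001 were the cardiac troponin gene Tnnt2 (−3.74), Srpx2 (−3.59), Mx1 (−3.50), E2f8 (−3.11), Rgs5 (−2.83), the sterol reductase Tm7sf2 (−2.79) and Scd (−2.78). The G protein regulator Rgs4 (−2.74), the growth factor Ptn (−2.69), Pde7b (−2.67), Fads2 (−2.56) and the amine oxidase Aoc3 (−2.46) followed. The decrease of Scd rested on the choice of vehicle array, since it differed by 0.05 from the vehicle of FJ9. Cholesterol genes had a median of −1.26 with 15 of 20 lower, led after Tm7sf2 by Stard4 (−2.22), Mvd (−2.11) and Idi1 (−1.86). Fatty acid genes had a median of −0.72 with 10 of 20 lower and 2 higher, among them the elongase Elovl6 (−2.08). Against the other vehicle the cholesterol median was −0.62, still called, and the fatty acid median was −0.12 and no longer called. Interferon genes were called below at −0.41, with 14 of 32 lower and 1 higher, led by Mx1, Ifit3 (−1.87), Oasl (−1.73) and Oas1a (−1.34), and had a median of −1.12 against the other vehicle. Cell cycle genes had a median of −0.56 with 12 of 26 lower and 1 higher, led by E2f8, the topoisomerase Top2a (−1.79), Rrm2 (−1.76) and cyclin B2 Ccnb2 (−1.45), and were not called against the other vehicle (−0.16, percentile 11.7). Glycolysis and hypoxia genes were called below at −0.40, with 11 of 32 lower and 1 higher, for example the lactate transporter Slc16a3 (−1.49), Ankrd37 (−1.39) and Pfkl (−1.30), while the glucose transporter Slc2a3 read 1.47.

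With ICG-001, collagens and other matrix genes had a median of −0.18 with 4 of 31 lower and 2 higher, led by Eln (−2.38), and this call ended against the other vehicle (−0.04, percentile 28.6). Lists of myofibroblast genes (0.07), matrix proteases (−0.18), quiescent genes (−0.10), oxidative stress (0.09) and chemokines (−0.22) lay inside the central 95%. The chemokine list became −0.65, below all random lists, against the other vehicle, and was called below after loess correction too (−0.29, percentile 2.02). Matrix proteases were called below after loess correction (−0.24, percentile 2.13). Named members were Inhba (1.27), calponin Cnn1 (1.09), Tgfb2 (0.94), Adamts1 (1.92), Vcan (0.93), Lrat (−1.42), Cebpa (0.82), the adhesion molecule Vcam1 (−2.07), Il33 (−1.99) and Gsta4 (−1.91). Col1a1 differed by −0.18, Pparg by 0.01 and Ndn by −0.01.

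FJ9 was compared with its vehicle to ask which genes need the link from Frizzled to Dishevelled. Ccnd1 differed by −2.94 and Axin2 by −2.54, while Myc (0.81) and Fosl1 (1.01) were higher. The Wnt target list had a median of −0.04, with 5 of 16 higher and 4 lower, including the matricellular gene Ccn4 (−1.69). The component list was called below at −0.24, with 17 of 43 lower and 4 higher, among them Sfrp1 (−3.32) and the receptors Fzd4 (−1.83) and Fzd2 (−1.46), against the antagonist Wif1 (1.40), and had a median of −0.50 against the other vehicle. Ctnnb1 differed by −0.51 and Lef1, under the level filter, by −0.57.

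With FJ9, 1160 genes were at least 1.5-fold higher and 1484 lower. Star, which carries cholesterol into mitochondria, was the largest increase (5.15), followed by the metallothioneins Mt1 (4.56) and Mt2A (3.52), the phosphatase Dusp2 (4.47) and Abcb1a (3.42). Cyp4b1 (3.28), the cystine transporter Slc7a11 (3.20), heme oxygenase Hmox1 (3.01), Pappa (2.89), Trib3 (2.84), the stress cytokine Gdf15 (2.82) and Stmn1 (2.72) completed them. Oxidative and xenobiotic stress genes had a median of 0.74, above all random lists, with 19 of 33 members higher and 1 lower, and Nqo1 in that list read 2.499. Mt1 and Mt2A, which are close in sequence, also differed by 1.08 and 1.56 between the vehicle arrays. The unfolded protein and amino acid response list had a median of 0.70, above all random lists, with 22 of 38 higher and 2 lower, including Ppp1r15a (2.04) and Slc3a2 (1.63).

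The largest decreases with FJ9 were the caveolar coat gene Cavin2 (−5.04), Scd2 (−4.27), Mx2 (−4.16), Cd200 (−4.07), Fads2 (−3.87), the transglutaminase Tgm2 (−3.83) and Mx1 (−3.70). Olfml1 (−3.56), Idi1 of isoprenoid synthesis (−3.55), Srpx2 (−3.49), Akap5 (−3.48) and Sema7a (−3.38) followed. Cholesterol genes had a median of −1.83 with 17 of 20 lower and none higher, including Acat2 (−2.65), Dhcr7 (−2.50) and Nsdhl (−2.10). Fatty acid genes had a median of −0.47 with 8 of 20 lower and 1 higher, including Scd (−2.49), which shares sequence with Scd2, and a median of −0.90 against the other vehicle. Interferon genes had a median of −1.54 with 27 of 32 lower and none higher, including Samd9l (−3.22) and Isg15 (−3.10). Against the other vehicle this median was −1.19, still called. Mx2 was the largest increase on the vehicle array of FJ9 over that of ICG-001, so part of its fall rested on the vehicle used. Myofibroblast genes had a median of −0.74, below all random lists, with 17 of 26 lower and none higher, led by S100a4 (−2.02), Cnn1 (−1.92), the myosin genes Myl9 (−1.73) and Myh11 (−1.71). YAP and serum-response genes had a median of −0.57 with 12 of 27 lower and 2 higher, led by Egr2 (−1.81), Edn1 (−1.72), Vcl (−1.61) and Egr1 (−1.34). Collagens and other matrix genes were called below at −0.34 with 12 of 31 lower, led by Lum (−2.47), Mfap4 (−1.35) and Col5a1 (−1.30), and Col1a1 differed by −0.23. Matrix proteases were called below at −0.54 with 10 of 22 lower and 1 higher, led by Reck (−1.76), Plau (−1.33), Adamts9 (−1.26) and Mmp16 (−1.16). Lists of quiescent genes (−0.02), cell cycle (−0.01), chemokines (0.00), p53 targets (−0.23) and glycolysis (−0.11) lay inside the central 95%, although single members moved, among them Lrat (−3.34), Cebpa (1.41), Hmmr (1.96), Mcm7 (1.65), Il33 (−3.02), Gadd45a (2.39), Cdkn2a (−1.65) and Slc16a3 (−2.12). Pparg, under the level filter, differed by 0.38 and Ndn by −0.98.

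**Figure D1:**
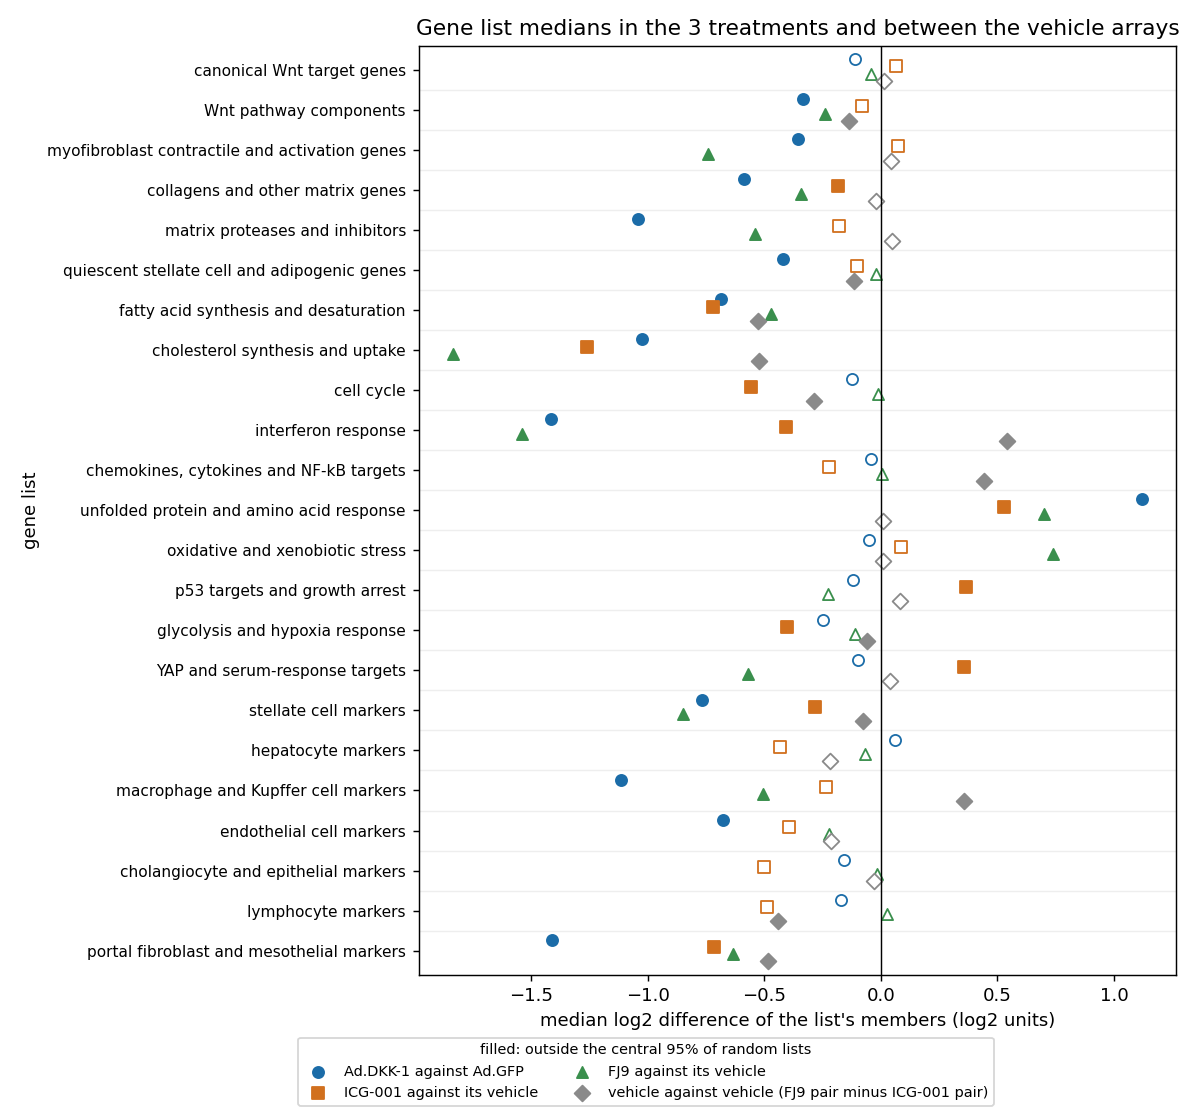
Median log2 difference (horizontal axis, log2 units) of each of the 23 gene lists under Ad.DKK-1 (circles), ICG-001 (squares) and FJ9 (triangles) and between the vehicle arrays (diamonds), with filled symbols for medians outside the central 95% of random lists. Cholesterol genes lie at −1.02, −1.26 and −1.83 and the unfolded protein list at 1.12, 0.53 and 0.70, while the canonical Wnt target list lies between −0.11 and 0.07.

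Between the vehicle arrays, 245 genes were at least 1.5-fold higher and 521 lower on the vehicle array of FJ9, 7.64% of genes. The split turned to 575 higher and 265 lower with median centring, 456 and 409 with repeated quantile normalization, and 314 and 419 with loess correction. The largest increases were Mx2 (2.15), the chemokine genes Cxcl1 (2.07), Ccl7 (1.78) and Ccl2 (1.66), and Lbp (1.83). The others were Mt2A (1.56), Tlr2 (1.43), Dpysl3 (1.38), Lrig3 (1.32), Birc3 (1.25), Map3k7cl (1.24) and Fibin (1.24). The largest decreases were Scd (−2.83), Ttc36 (−2.65), Slc30a10 (−2.61), Fads1 (−2.31), Igsf10 (−2.17), Col6a4 (−1.97), Rasgrp4 (−1.80), Igfbp5 (−1.62), Cox6b2 (−1.61), Oprl1 (−1.56), Them5 (−1.54) and Epb41l4a (−1.54). Interferon genes had a median of 0.54 with 16 of 32 higher, and chemokines and NF-kB targets 0.44 with 8 of 19 higher and 2 lower, each above all random lists. Fatty acid (−0.53) and cholesterol genes (−0.52) were below all random lists, and cell cycle genes (−0.29), quiescent genes (−0.12) and glycolysis genes (−0.06) were called below by smaller amounts. The values of quiescent and glycolysis genes change sign with median centring and were not called with unmatched random lists (percentiles 2.99 and 6.61), and the cell cycle call ended with loess correction (−0.16, percentile 5.83) and with repeated quantile normalization (−0.13, percentile 5.74). By median, lipid genes were therefore lower and interferon genes higher on the FJ9 vehicle than on the ICG-001 vehicle, without either compound. Not all members moved: 8 of 20 fatty acid and 7 of 20 cholesterol genes were at least 1.5-fold lower, and 0 higher.

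The comparisons were then set side by side to find changes that blocking the pathway at 3 steps had in common. Of 624 genes past 1.5-fold in all 3 treatments, 242 were higher in all 3 and 315 lower in all 3, where independent lists would give 21.2 and 40.4. The 6 mixed patterns held 2 to 19 genes each, 67 together. With median centring the same-direction genes numbered 374 higher and 234 lower. Across genes, which are not independent replicates, the log2 differences of any 2 treatments correlated with Pearson's r of 0.46 (Ad.DKK-1 and ICG-001), 0.45 (Ad.DKK-1 and FJ9) and 0.45 (ICG-001 and FJ9), and no array is shared between them. Of the same-direction genes, 12.03% also differed at least 1.5-fold between the vehicle arrays (3.72% of the higher and 18.4% of the lower), beside 7.64% of all genes.

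**Figure D2:**
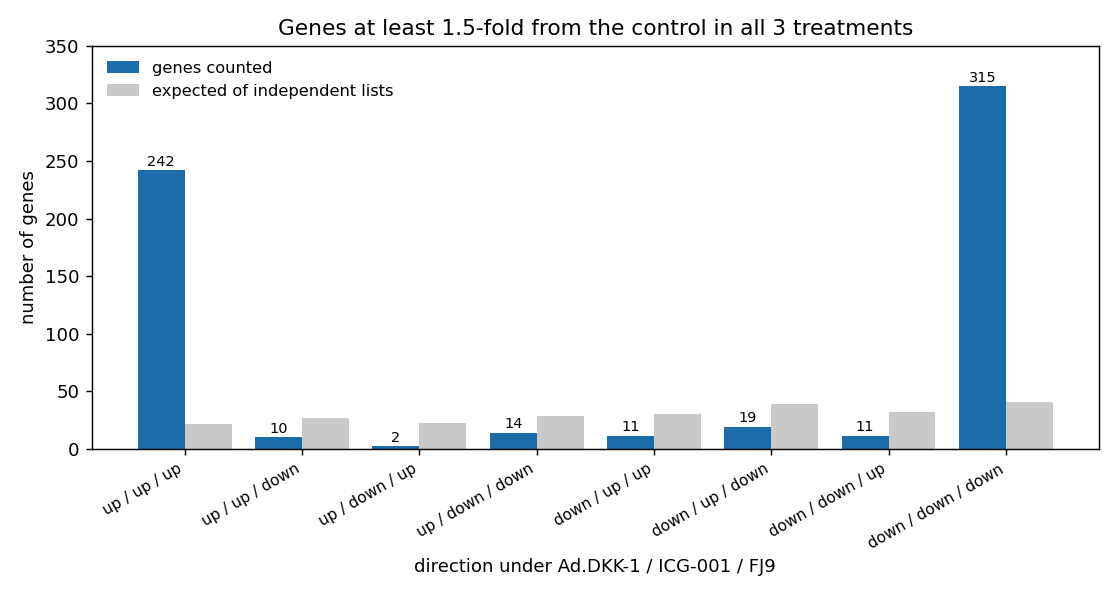
Number of genes (vertical axis) at least 1.5-fold from the control in all 3 treatments, by direction under Ad.DKK-1, ICG-001 and FJ9 (horizontal axis), with the number expected of independent lists in grey. The patterns higher in all 3 (242 genes) and lower in all 3 (315 genes) stand above the mixed patterns, which hold 2 to 19 genes.

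Across the 3 pairs, limma called 357 genes higher and 503 lower at an adjusted p under 0.05 of 10025 tested. The split was 291 higher and 247 lower with median centring. Of the genes past 1.5-fold in all 3, 219 of the 242 higher and 289 of the 315 lower were among these calls. Each ± value here is limma's moderated SE, which leans on the spread pooled over genes. It can be smaller than the spread of a gene's own 3 differences. Cth rose by 2.74 ± 0.25 (limma adjusted p = 4.94e-05), Abcb1a by 3.22 ± 0.33 (limma adjusted p = 0.000117) and Pappa by 2.44 ± 0.26 (limma adjusted p = 0.000125). Trib3, Ppp1r15a, the peptide hormone gene Adm2, the transcription regulator Akna, the translation factor subunit Eif2b3, the glutamine transporter Slc1a5, Stc2, Anks6 and Car8 also rose, each by at least 1.34 in every treatment. Mx1 fell, with a mean difference of −3.50 ± 0.24 (limma adjusted p = 5.70e-06). Vcam1 (−2.38 ± 0.24, limma adjusted p = 9.63e-05), Il33 (−2.34 ± 0.26, limma adjusted p = 0.000166) and Sfrp1 (−2.51 ± 0.28, limma adjusted p = 0.000166) fell as well. Scd, Fads2, Igfbp5, the interferon-induced genes Cmpk2, Ifi47, Uba7 and Ifit3, and Sphkap also fell. Scd (−2.83), Igfbp5 (−1.62) and Fads2 (−1.43) were lower on the vehicle array of FJ9 than on that of ICG-001. Their falls are thus larger with ICG-001 and smaller with FJ9 than against the other vehicle. Ad.DKK-1 was compared with neither vehicle array. Myc rose by 0.86 ± 0.19 (limma adjusted p = 0.0120). Axin2 (−1.54 ± 0.35, limma adjusted p = 0.0157) and Ccnd1 (−1.37 ± 0.35, limma adjusted p = 0.0278) fell, although both stayed within 1.5-fold of the vehicle with ICG-001. Scd2 fell by 2.27 ± 0.41 (limma adjusted p = 0.00385). Col1a1 (−0.20 ± 0.17, limma adjusted p = 0.4999), Ctnnb1 (−0.24 ± 0.20, limma adjusted p = 0.470) and Ndn (−0.65 ± 0.22, limma adjusted p = 0.0868) did not pass.

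By list, limma called 20 of 38 unfolded protein and amino acid response genes higher (25 adjusted over the list alone) and none lower, and 17 of these 38 were past 1.5-fold higher in all 3. Of 20 cholesterol genes 17 were called lower (18 adjusted over the list alone), of 32 interferon genes 22 (23 lower and 1 higher adjusted over the list alone) and of 20 fatty acid genes 9 lower and 1 higher (12 and 1 adjusted over the list alone). Scd and Fads1 among the 9 differed by 0.05 and 0.73 with ICG-001 against the other vehicle, where the ICG-001 call of the fatty acid list ended, and limma was not run with the vehicles exchanged. Of 33 oxidative stress genes 8 were called higher and 1 lower (10 and 1 adjusted over the list alone). The canonical Wnt target list had 2 of 16 higher, Myc and Fosl1, and 4 lower, Axin2, Nkd1, Ccnd1 and Ccn4 (4 and 4 adjusted over the list alone). The component list had 7 of 43 lower (7 lower and 1 higher adjusted over the list alone), including Sfrp1, Frzb and Fzd1. Matrix proteases had 7 of 22 lower (11 lower and 1 higher adjusted over the list alone), collagens and other matrix genes 6 of 31 (9 adjusted over the list alone), myofibroblast genes 5 of 26 (6 adjusted over the list alone) and glycolysis genes 5 of 32 (6 adjusted over the list alone). Quiescent genes had 3 of 20 lower (5 lower and 1 higher adjusted over the list alone), chemokines 3 of 19 (3 adjusted over the list alone), cell cycle genes 4 of 26 lower and 2 higher (6 and 2 adjusted over the list alone), p53 targets 2 of 22 higher and 1 lower and YAP and serum-response genes 1 of 27 higher and 4 lower, the same counts adjusted over the list alone.

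**Figure D3:**
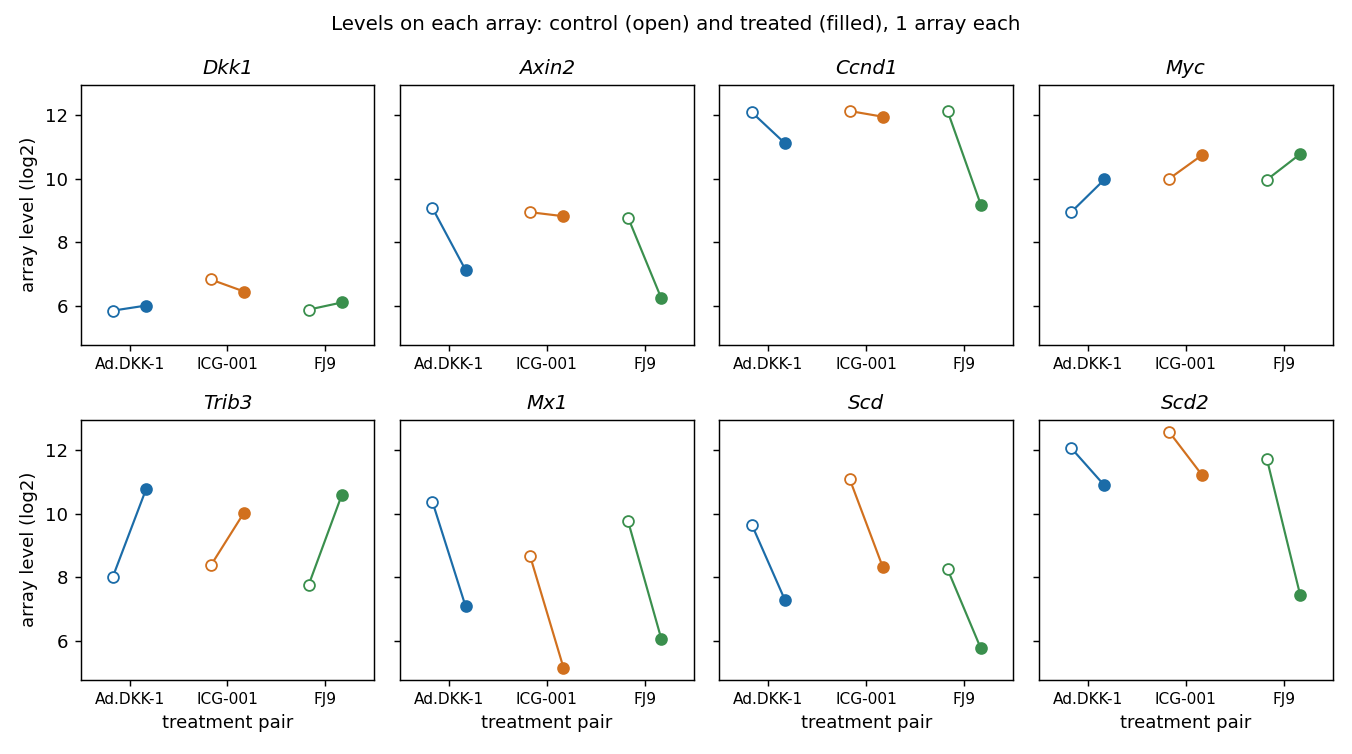
Log2 level (vertical axis) of 8 genes on the control array (open) and the treated array (filled) of each of the 3 pairs (horizontal axis), with 1 array per point. Trib3 and Myc are higher and Mx1, Scd and Scd2 lower on the treated array of each pair, Axin2 and Ccnd1 differ by −0.13 and −0.18 with ICG-001, and the control level of Scd in the FJ9 pair differs by −2.83 from that in the ICG-001 pair.

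Markers of the cell types that a stellate cell preparation can hold were measured in the same way. Stellate cell markers were called below in all 3 treatments, at −0.77 (13 of 17 lower), −0.28 (5 lower and 1 higher) and −0.85 (10 lower) for Ad.DKK-1, ICG-001 and FJ9, and at −0.07 between the vehicle arrays, a value that changes sign with median centring. They included Rgs5 (−3.12, −2.83 and −1.17), Pdgfra (−1.29, −2.33 and −1.29), the retinol acyltransferase gene Lrat (−1.31, −1.42 and −3.34) and Colec11 (−2.31, −1.20 and −1.22), and limma called 7 of 17 lower (8 adjusted over the list alone). Against the other vehicle the ICG-001 call ended (−0.24, percentile 3.12). Portal fibroblast and mesothelial markers were called below at −1.41, −0.72 and −0.63 with 6 of 11 lower each, and at −0.49 between the vehicle arrays. Without the level filter neither the FJ9 median (−0.22, percentile 3.55) nor the vehicle median (−0.17, percentile 14.7) was called, and against the other vehicle the medians were −0.41 with ICG-001 and −1.04 with FJ9. That list holds Eln, Lum and Mfap4 of the matrix list, together with Wt1 (−1.77, −1.44 and −0.91). Limma called 5 of 11 lower, the same number adjusted over the list alone.

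Macrophage and Kupffer cell markers were called below under Ad.DKK-1 (−1.12, 10 of 11 lower) and FJ9 (−0.51, 4 lower and 1 higher) but not ICG-001 (−0.23), and were 0.36 higher on the vehicle array of FJ9, beside the interferon and chemokine genes of that array. The other vehicle ended the FJ9 call (−0.08, percentile 60.7) and added an ICG-001 call (−1.08, below all random lists). Cybb (−1.62, −1.25 and −1.81), Fcer1g (−1.77, −0.997 and −1.10), Cd14 (−0.95, −1.11 and −1.47) and Csf1r (−0.92, −1.17 and −1.37) were the members lower in all 3, and limma called the same 4 (6 adjusted over the list alone). Endothelial markers were called below under Ad.DKK-1 (−0.68, 8 of 14 lower) and lay inside the central 95% with ICG-001 (−0.39) and FJ9 (−0.22), with Erg (−1.85, −1.56 and −1.86) and Flt1 (−1.71, −1.26 and −1.46) lower in each, and limma called 3 of 14 lower (3 adjusted over the list alone). Endothelial markers were called below with ICG-001 after loess correction (−0.36, percentile 1.29) and with FJ9 against the other vehicle (−0.44, percentile 2.27). Hepatocyte markers (0.06, −0.43 and −0.07), cholangiocyte markers (−0.16, −0.50 and −0.02) and lymphocyte markers (−0.17, −0.49 and 0.03) lay inside the central 95% in every treatment, over 8, 6 and 7 measured members, although lymphocyte markers were called below between the vehicle arrays (−0.44), a call that ended by the mean of the members (−0.31, percentile 5.98) and without the level filter (−0.37, percentile 4.51). With ICG-001, lymphocyte markers were called below after loess correction (percentile 2.46), repeated quantile normalization (1.88) and with unmatched random lists (2.04). Hepatocyte markers were called below with ICG-001 without the level filter (percentile 2.1) and with unmatched lists (2.08), and cholangiocyte markers with unmatched lists (1.71). Limma called 0 of 8 hepatocyte markers (0 at an unadjusted p under 0.05) and 0 of 7 lymphocyte markers (1 at an unadjusted p under 0.05), and 1 of 6 cholangiocyte markers, Anxa4, lower, with the same counts adjusted over the list alone. Over the 23 lists and 3 treatments, 37 of 69 medians lay outside the central 95%. Lists of randomly drawn genes would give 3.45, a number too low for lists whose members vary together. Between the untreated vehicle arrays 3 of the 23 lists lay above and 9 below, a similar share. The median and mean of the members differed in sign for 4 of the 69, none of them called by its median: chemokines with FJ9, oxidative stress genes under Ad.DKK-1, and hepatocyte markers under Ad.DKK-1 and FJ9. By the mean, chemokines with FJ9 were called below (−0.58, percentile 0.09) and oxidative stress genes under Ad.DKK-1 above (0.17, percentile 98.0).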

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

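The comparisons in this part were chosen after the values were seen.

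Probe sets without a gene name were not counted in the comparisons above. Of 6326 unnamed probe sets past the level filter, 231 lay at least 1.5-fold from the control in the same direction in all 3 treatments, 81 higher and 150 lower, and 29 in mixed directions. Of the 10025 named genes, 557 moved in the same direction in all 3. Between the vehicle arrays 165 of the unnamed probe sets were at least 1.5-fold higher and 641 lower, beside 766 of the 10025 named genes in either direction.

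The median of YAP and serum-response genes had opposite signs with the 2 compounds. It was 0.36 with ICG-001 (8 of 27 members at least 1.5-fold higher and 5 lower) and −0.57 with FJ9 (2 higher and 12 lower), each outside the central 95% of random lists. Edn1, the endothelin gene, read 1.40 and −1.72. The median of the gene-by-gene difference, FJ9 minus ICG-001, was −0.73, below all 10000 random lists, which describes these arrays and is no test of the difference, since each compound has 1 array. Against the other vehicle the ICG-001 median was 0.20 and lay inside the central 95%, as did the mean of the members against its own vehicle (0.18, percentile 94.95).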

How the results depend on the processing

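The counts of genes past 1.5-fold from both vehicle arrays, of genes whose vehicle arrays differ by less than 1.5-fold, and of the same-direction genes without each treatment were chosen after the data were seen, and the other alternatives before. In each pair of numbers the higher genes come before the lower. A 2-fold threshold left 400 and 793 genes for Ad.DKK-1, 290 and 329 for ICG-001, 245 and 601 for FJ9, 31 and 83 for the vehicle arrays and 43 and 111 in the same direction in all 3. Without the level filter the lower genes were 3236 for Ad.DKK-1 and 2337 for ICG-001, and the vehicle arrays gave 410 and 1123. Leaving out the lowest 50% gave 1304 lower genes for Ad.DKK-1, 622 for ICG-001, and 128 and 168 for the vehicle arrays. Median centring gave 2218 and 754 for ICG-001, 575 and 265 for the vehicle arrays, 374 higher in all 3, and 247 lower by limma, and repeated quantile normalization gave 456 higher for the vehicle arrays. Past 1.5-fold from both vehicle arrays were 835 and 739 genes for ICG-001. Fewer treatments asked for gave more same-direction genes: 431 higher without the Ad.DKK-1 pair, 436 and 722 without ICG-001, and 422 and 607 without FJ9. The same-direction genes numbered 192 and 233 when both compounds had to pass against both vehicles, and 233 and 257 among genes whose vehicle arrays differed by less than 1.5-fold.

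With limma, no pair block gave 167 and 255 genes, no trend 221 higher, an adjusted p under 0.1 gave 636 and 793, and leaving out the ICG-001 pair 165 higher. The 2-fold counts follow from the threshold. The centred fold counts follow from the array medians, whose difference (−0.17 for ICG-001, −0.13 for the vehicle arrays) centring takes from every gene. For the limma, level filter and quantile counts the cause was not tested. Over its other alternatives the higher count was 265 to 365 and the lower 366 to 557.

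Against the other vehicle array, 6 named genes reversed. With ICG-001 these were Ccl7 (−1.13), Fads1 (0.73) and Slc30a10 (0.88), and with FJ9 Lbp (1.14), Rasgrp4 (−0.93) and Ttc36 (−1.39). All 6 differed by over 1.5-fold between the vehicle arrays. A further 105 of 530 named values crossed 1.5-fold with that choice, 56 with the mean of both vehicles, 35 of 786 with loess correction and 1 with the mean of all probe sets (Klf4 under Ad.DKK-1, 0.71). Alternatives were run on the 23 lists fixed in advance and not on the 5 chosen after the data were seen. No called list median reversed under these alternatives, which left out median centring. That centring turns the sign of 4 called vehicle medians, those of the quiescent, glycolysis, stellate marker and amino acid supply lists, and leaves percentiles as they were. Of 46 list medians of the compounds, the other vehicle ended 6 calls and added 3, and of 92 in all, loess ended 3 and added 4, unmatched random lists 6 and 5, no level filter 5 and 6, and the mean of members 4 and 8. Cholesterol, interferon and unfolded protein lists were called in all 3 treatments under every alternative run. The precision is limited by 1 array per group, and values near the floor at 4 compress differences.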

Other observations

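The 5 further gene lists of this part, the split of the unfolded protein list, and the tests of the Axin2, amino acid, protein-folding and Myc explanations, were chosen after the values were seen, and the loess, vehicle difference and pair turning tests before.

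Of the 38 measured members of the unfolded protein list, 11 act in protein folding and secretion and 14 in amino acid supply or transfer RNA charging. The 11 had medians of 1.49 under Ad.DKK-1, −0.25 with ICG-001 and −0.39 with FJ9, and none was at least 1.5-fold higher with either compound, while the 14 had medians of 1.03, 0.84 and 0.9982. A wider list of 40 genes of protein folding and secretion in the endoplasmic reticulum, 36 of them measured, had a median of 0.75 under Ad.DKK-1, above all 10000 random lists, with 22 genes at least 1.5-fold higher and 1 lower. Its median was −0.21 with ICG-001 (percentile 0.2, 6 lower) and −0.30 with FJ9 (percentile 0.94, 7 lower), and 0.07 between the vehicle arrays. Derl3 read 4.91 under Ad.DKK-1, −0.22 with ICG-001 and −0.29 with FJ9, the co-chaperone Dnajb9 2.20, −0.05 and 0.26, Sdf2l1 1.88, −0.73 and −0.56, and the calcium-binding chaperone Calr 0.51, −0.82 and −0.77. By contrast, a wider list of 29 genes of amino acid supply and transfer RNA charging had medians of 0.998, 0.72 and 0.83, each above all random lists, with 26, 21 and 22 higher and 16 of them higher in all 3, among them Cth, Slc1a5, Slc7a1 and Psat1. That median was −0.06 between the vehicle arrays, where median centring changes its sign.

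Genes of ribosome biogenesis were higher in all 3 treatments. Of 66 measured, 46 were at least 1.5-fold higher under Ad.DKK-1 (median 0.73), 38 with ICG-001 (0.61) and 43 with FJ9 (0.67), and 28 in all 3, among them Polr1b (1.40, 1.25 and 1.06) and Rrp9 (1.26, 1.31 and 0.92). The median was 0.16 between the vehicle arrays, also above the central 95%. Pericyte genes had medians of −1.12, −0.52 and −0.66, with 11, 6 and 8 of 14 lower and 0, 2 and 1 higher, led by Rgs4 (−2.80, −2.74 and −1.76) and Rgs5, which the stellate marker list also holds. Genes of class I antigen presentation had medians of −0.58, −0.63 and −0.54, with 10, 11 and 10 of 20 lower, led by the histocompatibility gene RT1-S3 (−1.82, −1.22 and −1.998), and 0.19 between the vehicle arrays. Class I genes are close in sequence, and their probe sets can share signal.

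The number of genes moved the same way in all 3 treatments far exceeds the mixed patterns. A level-dependent difference between arrays as the whole cause is argued against by the 560 same-direction genes counted after loess correction, beside 19 in the largest mixed pattern. Between the vehicle arrays 12.03% of these genes differed at least 1.5-fold (3.72% of the higher and 18.4% of the lower), beside 7.64% of all genes, and since 1 pair of untreated pools does not show how the other pools differ, pool differences stay open. With the 3 pairs turned in the 4 possible ways, 1 of 4, the real one, gave as many genes past limma's adjusted p under 0.05 (860, and 0 for the highest other, with 105 to 189 at an unadjusted p under 0.05), and 4 ways are too few for a share under 0.05. A response to toxicity common to the treatments also stays open, since it was not measured apart from a shared loss of Wnt signalling. For such a loss, the canonical Wnt target list had medians of −0.11 under Ad.DKK-1, 0.07 with ICG-001 and −0.04 with FJ9, none of them called. Of its 16 members, 0 were at least 1.5-fold lower in all 3 treatments and 2 were higher. Limma called 4 members lower and 2 higher. The list as a whole thus shows no fall shared by the 3 treatments, and a loss limited to some of its genes stays open.

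As a hypothesis, the shared change may hold an amino acid response. If so, genes of the unfolded protein and amino acid list should be over-represented among those higher in all 3, and 17 of 38 were, against at most 3 in the central 95% of random lists. A shared rise of folding and secretion genes is argued against by the wider folding list, whose median was −0.30 with FJ9 and below the central 95% with both compounds. A response to protein-folding stress without that rise stays open. Ddit3, Ppp1r15a, Atf3 and Atf6 of the unfolded protein list were past 1.5-fold higher in all 3. That ribosome biogenesis genes follow a shared higher level of Myc is a further hypothesis: Myc was higher by at least 0.75 in each treatment and the list lay above the central 95% each time. The list also lay above it between the vehicle arrays (0.16), a comparison that the Myc test did not cover. The amino acid and Myc tests were passed on the data that gave the idea, and the folding list was chosen on the same data. A common cause of Myc and the ribosome biogenesis list was not tested.

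The vehicle arrays, which should differ little, differed in sterol synthesis and interferon genes. A level-dependent difference is argued against for the sterol list, whose median was −0.55 after loess correction. Differences between the pooled animals, the cultures or the vehicle solutions stay open, because the labels describe both controls in the same words, and no biological explanation was tested.

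Dkk1 was not clearly higher on the array labelled Ad.DKK-1 (0.16). Axin2, which DKK-1 should lower, read −1.96 on the array so labelled, against a difference of 0.17 in size between the vehicle arrays. That is the direction without a swap with Ad.GFP, but the test was set after the values were seen and cannot decide. It rests on a single gene of the canonical Wnt target list, of which 4 of 16 members were at least 1.5-fold higher on that array and 6 lower. A swap thus stays open. A virus insert that this rat probe set does not measure stays open, and its sequence was not analysed here.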
